A study of Mus musculus with 39 samples.

How the data were processed

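Single-cell RNA sequencing was done on 39 cells of 1 sorted population of mouse bone marrow progenitors, captured on a Fluidigm C1 system, with SMARTer cDNA and Nextera XT libraries, per the labels' protocols. The deposited values are log2 values of TPM plus 1 for 23955 genes, as the table itself shows: taken back to the linear scale, each column summed to 1000000 TPM and 99.999% of values lay within 0.01 of a step of a 0.01 TPM grid. RSEM, Bowtie2 and the mm9 build are named in the submitters' processing notes, without versions or settings, and the annotation is not given in the sources used here. TPM keeps no read counts, so the depth per cell is unknown and count models were not used. TPM values are shares of a cell's total, so 1 very abundant transcript lowers all others. The reference at hand was of another build, so no coordinates are given and genes are identified by symbol, of which 23819 matched a RefSeq symbol or synonym. Reads of near-identical genes may be split or shared in these values, which makes Ly6c1 and Ly6c2, Hspa1a and Hspa1b, Csf2rb and Csf2rb2, Ubb and Ubc, Prg2 and Prg3, the Fcgr and Mcpt families, and genes with many processed pseudogenes (ribosomal proteins, Eef1a1, Ppia) uncertain.

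Columns were matched to cells by the number in the title. The 37 cells without a quality remark formed 1 group, described with both title series together, and the 2 cells titled poor quality entered no summary apart from the alternative with all 39 cells. Because each library is 1 cell and no animal or culture is named, cells were not treated as replicates. Shares of cells are given with exact 95% Clopper-Pearson intervals, a count of 0 also with the share that 3 cells would give, and medians with order-statistic intervals. These intervals cover counting error only and say nothing about other mice.

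A gene was called detected at 1 TPM or more. The 19 gene lists, 10 pairs of regulators and 8 pairs of lists were fixed before the data were examined, and 186 of 188 list genes were among the table's symbols (Ly6g and Siglecf were not). Levels are the summed share of TPM per cell, given as medians and ranges in place of the planned mean and SD because 1 cell can dominate a mean and a 0 can be a missed transcript. A cell was counted for a lineage list when at least 3 members were detected. Co-variation is the mean pairwise Spearman correlation of log2(TPM + 1) over members detected in at least 4 cells. It was placed as a percentile among 10000 random lists in which each member was replaced by 1 of the 100 genes nearest in mean. Pairs of list scores and component loadings were placed in the same way. Joint detection was placed among random pairs of genes detected in the same numbers of cells. Variability is the excess of log10 squared coefficient of variation over a lowess trend (fraction 0.3) for genes with a mean of at least 10 TPM in at least 4 cells. Components were computed on the 500 most variable genes, centred and not scaled. All percentiles describe these 37 libraries and are not p-values.

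Genes named in the text are those of the gate and of the regulator pairs, up to 4 members of each list with the highest mean, further members detected in at least 3 cells for lists of other lineages, the 15 genes of highest mean, the 15 most variable, and 10 at each end of components 1 and 2. Other list members are named to complete a list, and Prss34, Gfi1b, Rn45s, the genes of cell 78, and individual cells were singled out after their values were seen.

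Simulated data were made by shuffling each gene over the cells, with 9093 genes in the step. A shared factor of 0.5 SD was recovered beyond the upper bound in 10 of 10 lists. A factor of 1 SD was recovered in 10 of 10, against 1 of 20 unchanged lists. Each simulated list had 10 members, so recovery in shorter lists was not tested. All 5 of 5 planted pairs of lists were recovered and 0 of 5 unchanged pairs lay outside the bounds. All planted lists carried the same factor, so these recoveries were not independent of each other. Shuffling each gene on its own also removed the correlations between genes of the real cells, so the rates need not hold there. Component 1 correlated at 0.952 with a factor planted in 100 genes. These were entered directly beside randomly chosen genes, so the choice of the most variable genes was not tested. Raising 3 cells by 16 times the mean increased the excess variability of 81 of 100 genes, among 6783 genes. Raising them by 4 times increased that of 36 of 100, so the ranking favours large peaks. Peaks in more or fewer cells were not compared.

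Alternatives were detection at 5 TPM or at any value above 0, 2 members for a lineage list, all 39 cells, each title series alone, the 10 cells with the fewest genes left out, pseudocounts of 0.1 and 10 TPM, removal of a linear term in detected genes, median-ratio rescaling over 384 genes, Pearson correlation, members in at least 10 cells, totals without the 15 most abundant genes, other mean filters, 200 or 1000 genes and scaled genes for the components. The sign of a component was set to follow the one reported, a rule made after sign flips had first been counted as reversals. Each cell was also left out in turn, with 2000 random lists, and joint detection was placed among random pairs at the other 2 thresholds, both added after the data had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.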

Results

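RNA was measured in individual granulocyte-monocyte progenitors (GMPs) from the bone marrow of C57BL/6 mice. GMPs are bone marrow cells that give rise to neutrophils and monocytes. The cells had been sorted as lineage-negative and Sca1-negative, positive for CD117, CD16/32 and CD34, and negative for CD115, the receptor for macrophage colony-stimulating factor. They also carried a green fluorescent reporter of Gfi1, a repressor needed for neutrophil development, at a level that the labels call dim in some places and intermediate in another. Of 39 libraries, 37 were cells without a quality remark and 2 were titled as poor quality and kept apart. Among the 37, 26 had a plain number in the title and 11 a number with the prefix R2, which the labels do not explain. No animal was named, so the 37 cells counted as 1 sample, no significance test was run, and every interval covers counting error alone. Values are TPM, transcript shares scaled to a total of 1000000 per cell, which keep no trace of sequencing depth, so the depth of each cell is unknown.

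The most abundant transcripts included general housekeeping RNA and 2 neutrophil granule enzymes. By mean TPM over the 37 cells the leading genes were Eef1a1, Mpo, Actb, Ubb, Ppia, Rps18, Rpl41, Gpx1, Plac8, Elane, Rps19, Ptma, Rpl32, Rps14 and Rpl3. Mpo, which encodes the myeloperoxidase of primary granules, had a mean of 11565 TPM and ranked behind the translation factor Eef1a1 alone (13482 TPM). Elane, which encodes neutrophil elastase, had a mean of 6051 TPM. A cell held a median of 4439 genes at 1 TPM or more (95% order-statistic interval 4249 to 4652, range 2453 to 5722). Medians were 4472 genes in the 26 plainly numbered cells and 4414 in the 11 R2 cells. Across the 37 cells 11787 genes were detected at least once and 384 in every cell. Pearson correlations of log2 values between pairs of cells had a median of 0.602 (range 0.447 to 0.711). The 6 housekeeping genes together took a median of 3.69% of TPM (range 2.54 to 5.46%), yet Hprt was listed at 0 in 1 cell, so a 0 elsewhere is reported only as listed at 0.

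The genes behind the sort gate served as a check of the labels and are not findings. Transcripts of the positive markers were frequent: Cd34 was detected in 36 of 37 cells (97.3%, 95% Clopper-Pearson interval 85.8 to 99.9%), Fcgr3 in 34 (91.9%) and Kit, which encodes CD117, in 32 (86.5%, 71.2 to 95.5%). Fcgr2b, the second gene read by the CD16/32 antibody, was detected in 20 cells (54.1%). Gfi1 itself reached 1 TPM in 14 cells (37.8%, 22.5 to 55.2%), with a median of 0.22 TPM and a maximum of 78.4 TPM. On the negative side, Cd3e, Cd3g, Cd4, Cd8a and Cd19 reached 1 TPM in none of the 37 cells, which allows a share of up to 8.11% for each by the rule of 3 counts and 9.49% by the exact 95% interval. Cd3d was detected in 1 cell, Gypa in 2, Cd8b1 in 4 and Itgam in 4, the last with a maximum of 16.6 TPM. Csf1r, which encodes CD115, was detected in 7 cells (18.9%, 7.96 to 35.2%), and cell 82 held 771 TPM against 105 TPM in the next cell. Ly6a, which encodes Sca1, was detected in 17 cells (45.9%) with a median of 0.64 TPM. Its highest value, 152 TPM, lay in cell 75, which also held the highest value of Ly6c2, another Ly6 gene (15410 TPM). Whether reads of Ly6c2 were counted as Ly6a was not tested, so these detections are uncertain. Together the positive gate genes took a median of 0.109% of TPM and the negative ones 0.000621%. CD45R is an isoform that gene-level values cannot show, and Ly6g is not among the symbols analysed here.

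**Figure D1:**
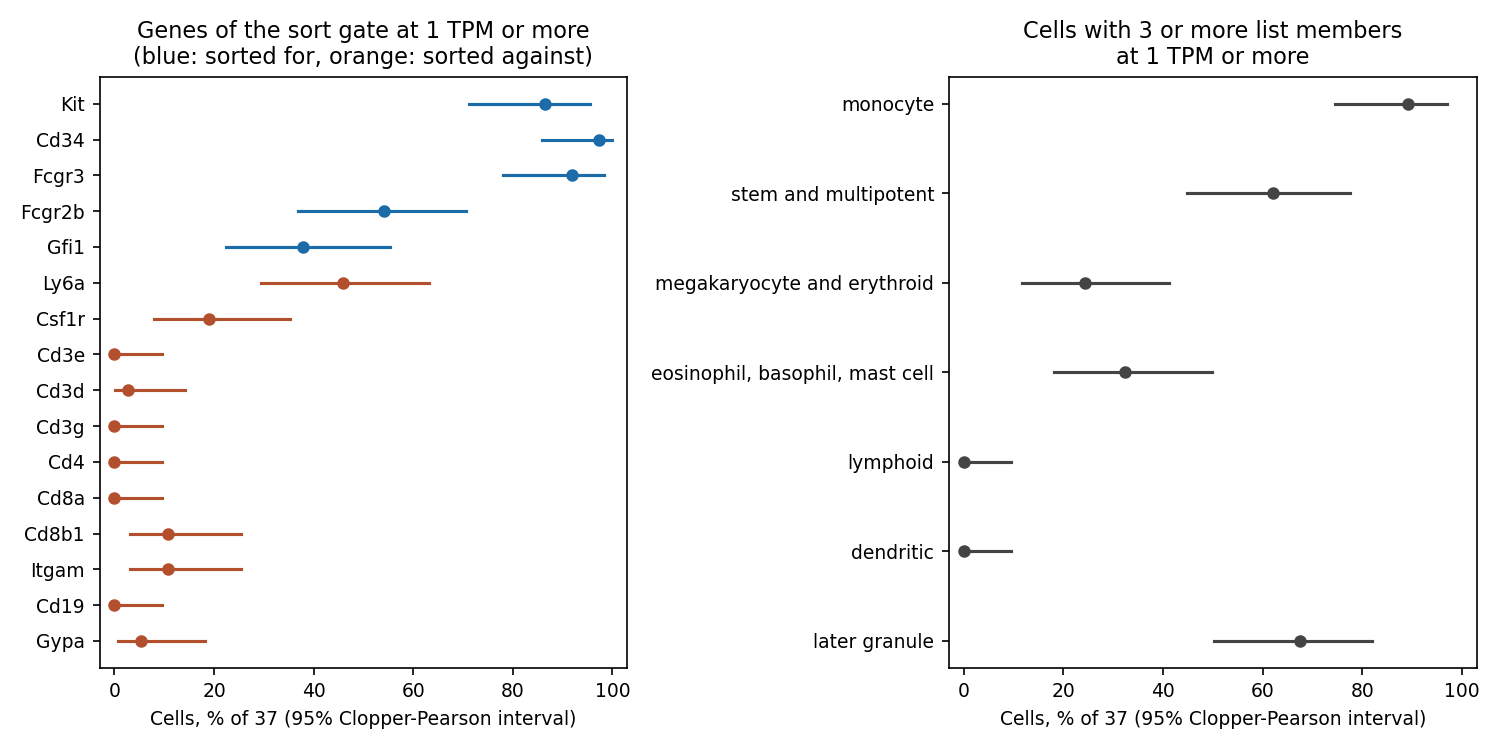
Left: share of the 37 cells with each gene of the sort gate at 1 TPM or more, in percent, with 95% Clopper-Pearson intervals; blue genes were sorted for and orange genes against. Right: share of cells with at least 3 members of each lineage list at 1 TPM or more, from 0% for the lymphoid and dendritic lists to 89.2% for the monocyte list.

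The question behind the series is how progenitors are ordered in development, and the fixed gene lists ask which programs cells of this gate expressed. Genes of primary granules, the first granules a neutrophil precursor forms, had the highest median share apart from the housekeeping list (3.69%). The list took a median of 2.94% of all TPM (2.17 to 3.20%), from 0.190% in cell R2.39 to 5.54% in cell 82. Mpo was detected in 37 of 37 cells with a median of 10336 TPM and a range of 39.3 to 26918 TPM. Elane (median 4916 TPM), Prtn3 (1845 TPM) and Nkg7 (1323 TPM) were also detected in all 37, and Ctsg in 36 (2065 TPM). Elane ranged from 8.40 to 19727 TPM. The median of the list was 2.77% in plainly numbered cells and 3.30% in R2 cells.

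Genes of later granules, made as neutrophils mature, were mostly rare. Ltf, Mmp9, Cd177 and Itgb2l were listed at 0 in all 37 cells, and Camp, Ngp, Mmp8 and Chil3 were each detected in 2 cells at no more than 17.3 TPM. Lcn2, which encodes lipocalin 2, was detected in 7 cells with up to 437 TPM, and Retnlg in 1 cell at 157 TPM. Anxa1, which other myeloid cells also express, was detected in 35 cells (median 442 TPM) and Pglyrp1 in 25. S100a8 and S100a9, which encode the subunits of calprotectin, were detected in 17 and 13 cells, yet 1 cell held 93.5% of all S100a9 TPM. The list took a median of 0.0641% of TPM. At least 3 of its members were detected in 25 cells (67.6%), and in 10 cells (27.0%) once Anxa1 was left out, a step chosen after the values were seen.

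Transcripts of granulocyte regulators were sparse: Cebpe, a regulator of late neutrophil and eosinophil genes, was detected in 12 cells (32.4%), Per3 in 19, Ets1 in 7 and Cebpd in 5. Together with Gfi1 they took a median of 0.0062% of TPM. Of the regulators shared by myeloid cells, Myb was detected in all 37 cells (median 281 TPM), Fli1 in 36, Lmo2 in 33 and Runx1 in 33. Lyz2, which encodes lysozyme, was detected in 30 cells (median 175 TPM), Cebpa in 24 and Spi1 in 20. That list had a median of 0.101% of TPM.

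Monocyte genes were present in many cells at uneven levels. At least 3 of 13 members were detected in 33 of 37 cells (89.2%, 74.6 to 97.0%). Ly6c2 was detected in 36 cells and Ms4a6c in 35, and without these 2 widely detected genes, again a later step, the count was 20 cells (54.1%). Ly6c2 had a median of 25.3 TPM and reached 15410 TPM in cell 75, with the reservation that its reads can be shared with its near-identical neighbour Ly6c1. Irf8, which directs monocyte and dendritic cell fate, was detected in 15 cells (40.5%, 24.8 to 57.9%) with a maximum of 675 TPM. Klf4, another monocyte regulator, was detected in 9 cells, F13a1 in 13, Ly86 in 10, Ccr2 in 15, Zeb2 in 26, Ctss in 12, Irf5 in 8, Mpeg1 in 5 and Cx3cr1 in 4. The share of TPM had a median of 0.0529% and a range of 0.000539 to 1.67%.

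Genes of stem and multipotent progenitors were detected alongside the granule genes. At least 3 of 10 members were found in 23 cells (62.2%, 44.8 to 77.5%). Gata2 was detected in 26 cells (median 51.8 TPM), Meis1 in 24 (9.53 TPM), Sox4 in 28, Hoxa9 in 14, Flt3 in 8, Hlf in 8 and Erg in 6. Procr was listed at 0 in all 37 cells, and Mecom and Mycn were each detected in 1. Gata2 is also considered below as a regulator of the eosinophil, basophil and mast cell lineage. Cell 85 held the highest Meis1 (3433 TPM) and Flt3 (1889 TPM), and the list took 0.553% of its TPM against a median of 0.0215%. Megakaryocyte and erythroid genes reached 3 of 13 members in 9 cells (24.3%, 11.8 to 41.2%). Car2 was detected in 19 cells, Itga2b in 12, Tal1 in 12, Gata1 in 9 and Zfpm1 in 4, whereas Klf1, Epor, Pf4, Car1, Hbb-b1 and Vwf were listed at 0 in all 37. Hba-a1 was detected in 1 cell, and the list had a median of 0.0106% of TPM. Gata1, like Gata2, is considered below as a regulator of the eosinophil, basophil and mast cell lineage. The 9 cells therefore do not by themselves show a separate megakaryocyte and erythroid program.

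Eosinophil, basophil and mast cell genes showed the widest range of any list. Their share of TPM had a median of 0.0756% but ran from 0 to 10.8%, and the next cell after the highest held 4.56%. Prg2, the major basic protein of eosinophil granules, reached 96296 TPM in cell 84 and 39243 TPM in cell 77, although it was detected in 7 cells in all. Mcpt8, a basophil protease, was detected in 21 cells and reached 26219 TPM in cell 95. Cpa3, a mast cell and basophil carboxypeptidase, was detected in 26 cells with a median of 427 TPM. Ms4a2, a chain of the high-affinity IgE receptor, was detected in 10 cells, Epx in 4, Prg3 in 3 and Il5ra in 3. At least 3 of 10 members were detected in 12 cells (32.4%, 18.0 to 49.8%), which were 11 of the 26 plainly numbered cells and 1 of the 11 R2 cells. This count includes traces, as the list took 0.000734% of TPM in cell 85 and 0.00297% in cell 91, both plainly numbered. In the other counted cells it took 0.0674% (cell 73) or more. Neither the count nor its split between the series therefore shows how many cells ran this program. Reads of Prg2 and Prg3, and of the mast cell protease family, can be shared between related genes.

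Lymphoid and dendritic programs were not detected. No cell held 3 or more members of either list, which allows a share of up to 8.11% of cells by the rule of 3 counts and 9.49% by the exact 95% interval. Cd79b, a B cell receptor component, was nevertheless detected in 18 cells with a median of 0.61 TPM and a maximum of 888 TPM, whereas the B and T cell genes Ebf1, Pax5, Il7r, Dntt and Rag1 were listed at 0 throughout. Rag2 (115 TPM), Cd79a (73.2 TPM) and Vpreb1 (12.55 TPM) were each detected in 1 cell. H2-Ab1 was detected in 11 cells and Xcr1 in 6, the latter at no more than 5.85 TPM. With any value above 0 counted, 10.8% of cells held 3 dendritic genes. The lymphoid and dendritic lists took medians of 0.000108% and 7.4e-05% of TPM.

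Replication genes were widely expressed. Mcm6 was detected in 33 cells (median 338 TPM), Pcna in 33 (289 TPM), Mcm3 in 36 and Mcm7 in 31, and S phase genes took a median of 0.247% of TPM. G2 and M phase genes took 0.0572%, with Birc5 in 26 cells, Top2a in 23, Ccnb2 in 22, Mki67 in 18 and Ccnb1 in 15. Genes of the secretory pathway took 0.728%, led by Calr (median 1270 TPM), Canx (1105 TPM) and Hspa5 (915 TPM), each in all 37 cells, with Pdia6 (480 TPM). Of the NADPH oxidase, which makes superoxide in phagocytes, Rac2 was detected in all 37 cells and Cyba in 36, whereas Cybb, the catalytic subunit, was detected in 11. Ncf4 and Ncf2 were detected in 22 and 29 cells, and the list took 0.108% of TPM. The cytokine receptor list took 0.0617%, with Cxcr2 in all 37 cells, Ifngr1 in 36, Csf2rb in 33, Csf3r in 24 and Tnfrsf1a in 21. Immediate early and stress genes, which respond within minutes to stimulation or handling, took a median of 0.125% and ran from 0.000437 to 1.51%. Fos was detected in 34 cells (median 644 TPM, maximum 8836 TPM), Jun in 33, Dusp1 in 30 and Egr1 in 22.

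Joint detection of regulators was examined because cells with factors of alternative fates are of interest in a hierarchy. Gfi1 and Cebpe were detected together in 9 cells (24.3%, 11.8 to 41.2%), against 4.54 cells from the product of their shares. This count lay at the 99.8 percentile of random gene pairs detected in the same numbers of cells. Irf8 and Gata2 were found together in 6 cells (16.2%, 6.19 to 32.0%) against 10.5 from the product, at the 0.04 percentile. Gfi1 and Irf8 shared 6 cells, against 5.68 from the product. The other pairs lay within the central 95% of random pairs: Irf8 with Cebpe in 4 cells, Gfi1 with Klf4 in 3, Irf8 with Klf4 in 3, Gfi1 with Gata2 in 11, Cebpe with Gata2 in 9, Gfi1 with Meis1 in 9 and Cebpe with Meis1 in 8. Transcripts missed in a library lower every such count, and both outlying pairs depended on the threshold. At 5 TPM, Gfi1 and Cebpe shared 4 cells (10.8%), at percentile 86.6, and Irf8 and Gata2 shared 5 against 9.08 from the product (percentile 0.235). With any value above 0 counted, Gfi1 and Cebpe shared 9 cells against 6.16 (percentile 95.6) and Irf8 and Gata2 shared 17 (45.9%) against 18.9 (percentile 3.80), so both then lay within the central 95%. Gfi1 and Irf8 shared 12 cells (32.4%) against 12.8.

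Members of several programs rose and fell together from cell to cell. The mean pairwise Spearman correlation was 0.430 among G2 and M phase genes, 0.411 among immediate early genes, 0.312 in the secretory list, 0.272 among S phase genes, 0.230 among primary granule genes and 0.168 among monocyte genes. Each of these 6 values lay above those of all 10000 random lists matched on mean expression. Among eosinophil, basophil and mast cell genes it was 0.328 (percentile 99.98) and among megakaryocyte and erythroid genes 0.193 (99.7). The other 9 lists with enough members lay within the central 95% of random lists. Negative gate genes gave 0.131, stem and multipotent genes gave 0.0441, later granule genes 0.0344, granulocyte regulators 0.0367, NADPH oxidase genes 0.103, housekeeping genes 0.0644, positive gate genes 0.00705, cytokine receptors -0.0122 and shared myeloid genes -0.0225. The megakaryocyte and erythroid value lay at percentile 87.6 in the plainly numbered cells alone, 88.9 over members in at least 10 cells, 87.2 after a linear term in detected genes was removed and 94.65 without cell 89. Its 5 members included Gata1, which is considered below with the eosinophil, basophil and mast cell lineage.

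**Figure D2:**
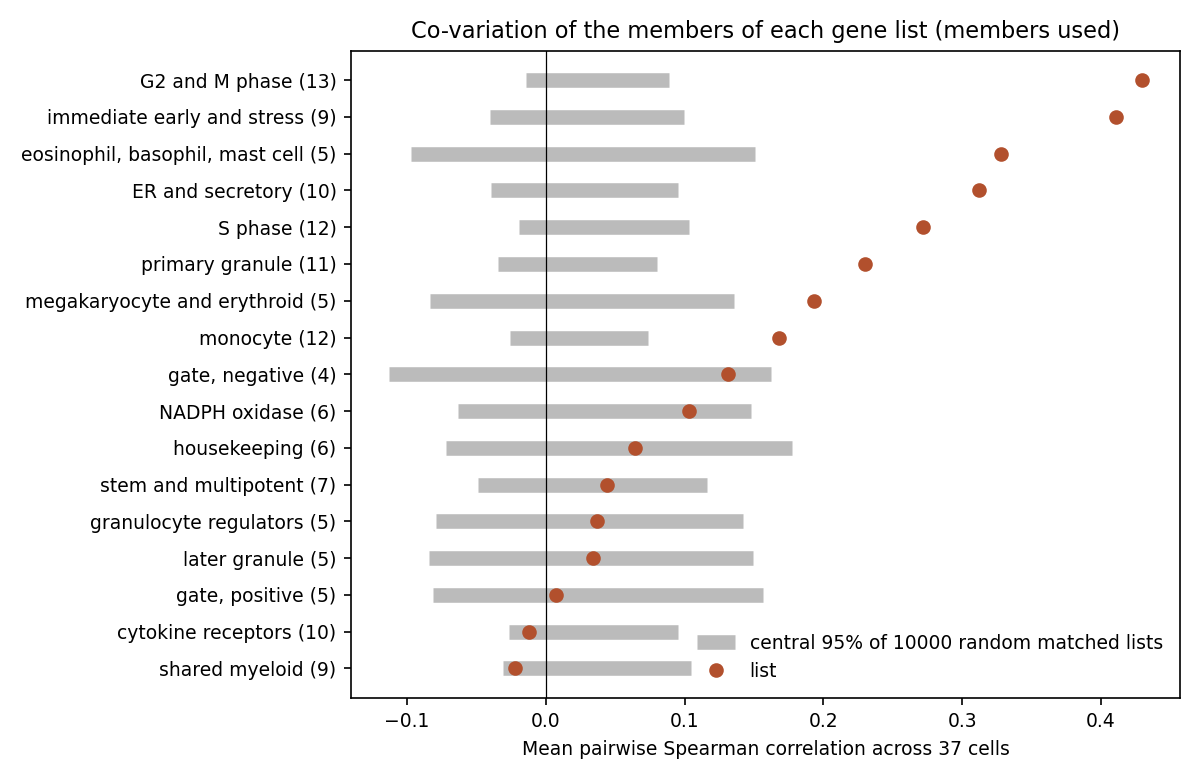
Mean pairwise Spearman correlation across the 37 cells of the members of each gene list (orange points), with the number of members used in parentheses; grey bars span the central 95% of 10000 random lists matched on mean expression. The highest value is 0.430 for the G2 and M phase genes, and 8 lists lie to the right of their grey bar.

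Scores of the lists, the mean z-score of their members in a cell, were then compared over the 8 pairs fixed beforehand. Primary granule and monocyte scores were positively related (Spearman rho 0.494, percentile 98.9 among random matched pairs of lists). Primary granule and stem scores were inversely related (rho -0.407, percentile 0.21), as were later granule and S phase scores (rho -0.197, percentile 1.34). The other 5 pairs lay within the central 95%: primary with later granule genes at 0.135, later granule genes with stem genes at 0.0481, with monocyte genes at 0.00284 and with G2 and M phase genes at 0.220, and granulocyte regulators with monocyte genes at -0.128. In the plainly numbered cells alone, primary granule and monocyte scores gave 0.430 (percentile 93.4). Primary granule and stem scores gave -0.245 in the R2 cells alone (percentile 24.3) and -0.196 in the 27 cells with the most genes (percentile 17.4), and later granule and S phase scores lay at percentile 6.41 after a linear term in detected genes was removed, 3.51 with Pearson correlation and 2.6 without cell 92.

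A further 5 pairs were chosen after the values had been seen. The eosinophil, basophil and mast cell score was inversely related to the primary granule score (rho -0.513, percentile 0.02) and to the monocyte score (rho -0.523, percentile 0.02). It rose with the immediate early score (rho 0.684, above all 10000 random pairs), although with Pearson correlation that relation lay at percentile 97.4, within the central 95%. Immediate early and primary granule scores were inversely related (rho -0.537, percentile 0.02). With the stem score the eosinophil, basophil and mast cell score gave 0.281 (percentile 85.8). In the 11 R2 cells alone its relation to the primary granule score was -0.610, at percentile 2.75.

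**Figure D3:**
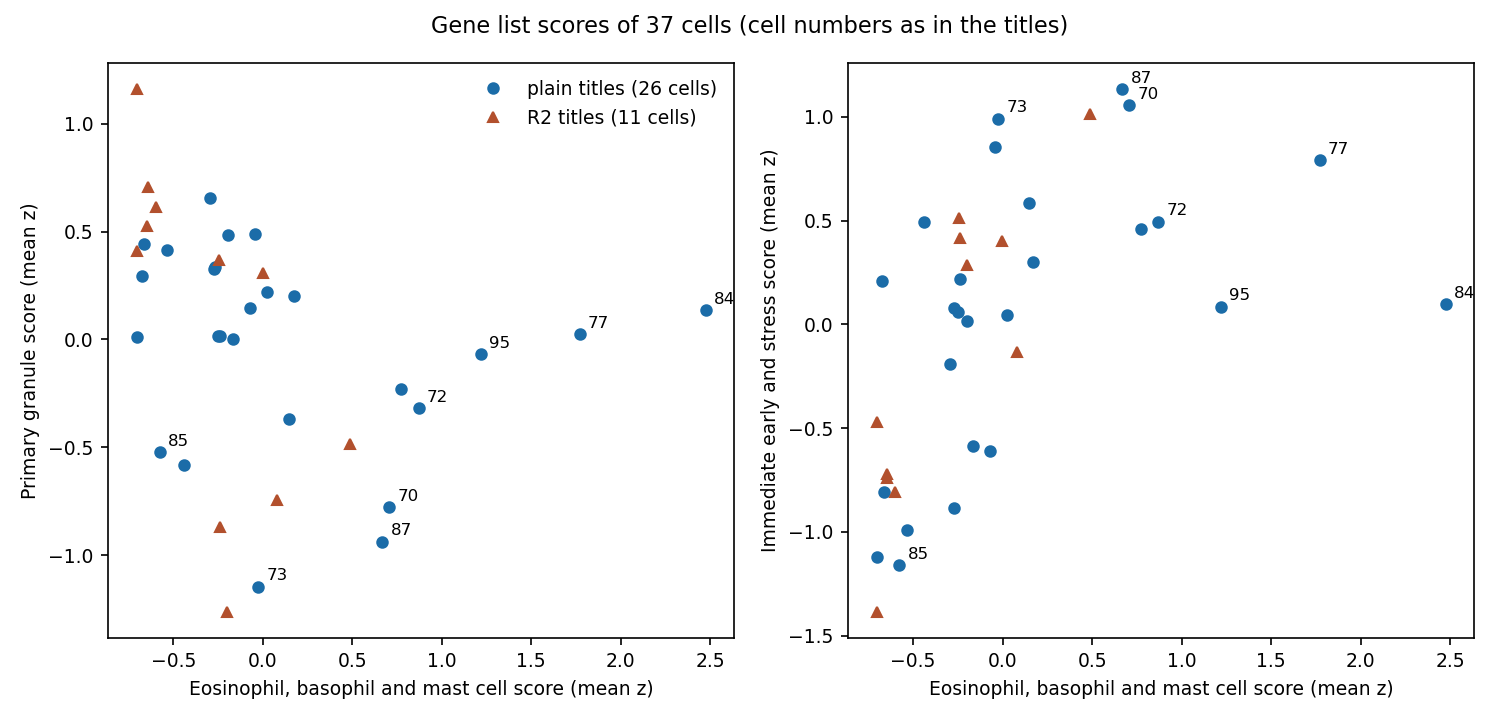
List scores (mean z-score of log2 values) of the 37 cells, with the eosinophil, basophil and mast cell score on the x axis and the primary granule score (left) or the immediate early score (right) on the y axis; circles are plainly numbered cells and triangles R2 cells, with 8 cells numbered. The Spearman correlation is -0.513 on the left and 0.684 on the right, and cell 84 lies farthest right in both panels.

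The most variable genes for their mean were Prg2, Prss34, Mcpt8, Ifitm1, Ly6c2, Epx, Elane, Mpo, Ropn1l, Ms4a2, Ubb, Cd63, Cpa3, Fos and I730030J21Rik, of 6783 ranked genes. Prss34, a basophil and mast cell protease, reached 59159 TPM in cell 95 and 31956 TPM in cell 72 but was detected in 11 cells. Ifitm1, an interferon-induced gene, was detected in 29 cells with a median of 146 TPM and a maximum of 20489 TPM in cell 73. Cd63, a granule membrane protein, ran from 0 to 7947 TPM. For 7 of these 15 genes 1 cell held most of the summed TPM, as cell 84 did for Epx (89.7%) and cell 85 for Ropn1l (96.0%).

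Without prior grouping, component 1 of the 500 most variable genes set granule and monocyte genes against basophil, mast cell and immediate early genes. It held 9.28% of the variance, against at most 4.95% when each gene was shuffled over cells. Ly6c2, Hp, Slpi, Elane, Clec12a, F13a1, Fam136a, Ly86, BC035044 and Tifab lay at the high end. The low end held Ms4a2, Cpa3, Gata2, Egr1, Dusp1, Csrp3, Ifitm1, Apoe, Angpt1 and Fos. Loadings of the primary granule and monocyte lists lay above those of all 10000 random lists, with S phase genes at percentile 98.6 and secretory genes at 98.2. Low loadings belonged to the immediate early list (below all 10000), the eosinophil, basophil and mast cell list (percentile 0.01), the megakaryocyte and erythroid list (0.03) and the stem list (0.6). List members such as Ms4a2, Cpa3, Mcpt8, Elane, Ly6c2 and Fos were among the 500 genes that built the components. Random lists were matched on mean alone, not on variability, which favours extreme loading percentiles for such lists on both components. Cell 87 had the lowest score, -0.417, followed by cells 73, R2.41 and 72, and cell 81 had the highest, followed by cells 75 and 92. All of these were among the 10 cells with the fewest detected genes, so both ends of this axis were held by such libraries. With those 10 left out, the primary granule list and the eosinophil, basophil and mast cell list stayed outside the central 95% on the same sides. In the 27 cells with the most genes the stem list lay at percentile 19.1 and S phase genes at 96.6, and the secretory list lay at 95.1 in the plainly numbered cells. Single cells also mattered, since the stem list lay at 9.6 without cell 72, S phase genes at 91.45 without cell 70 and the secretory list at 96.15 without cell 73. With genes scaled to unit variance the megakaryocyte and erythroid list lay at 23.2. Its lowest loadings were those of Itga2b (-9.99) and Gata1 (-9.74), against -4.15 for Car2, -0.758 for Tal1 and -0.459 for Zfpm1.

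**Figure D4:**
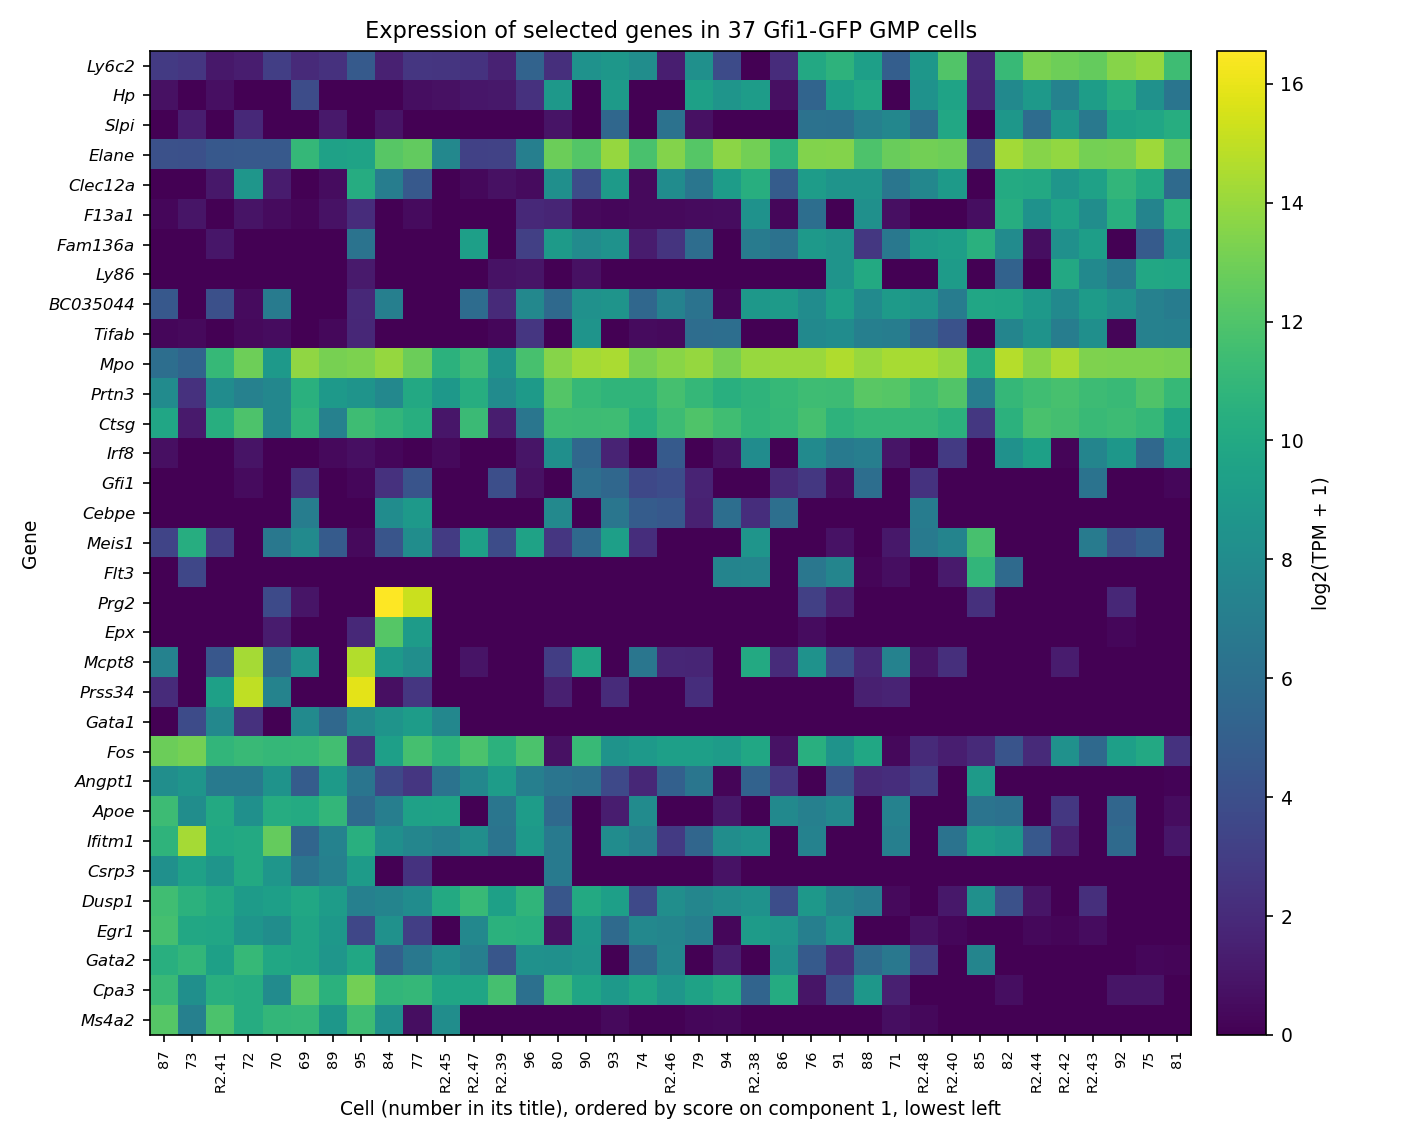
Expression as log2(TPM + 1) of the 10 genes at each end of component 1, with 12 further genes of the lists and Prss34 between them, in the 37 cells ordered by their score on component 1. Elane and Ly6c2 increase toward the right, Ms4a2, Cpa3 and Gata2 toward the left, and Prg2 is bright in cells 84 and 77, where Cebpe and Gata1 are also detected.

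Component 2 held 6.28% of the variance (at most 4.62% after shuffling) and rested on cell 85, whose score was -0.812 while the next lowest was -0.164. Its low end held Meis1, Fam117a, Car2, Lgals8, Trpv2, Ctla2a, Ptcd3, Smg9, Cd27 and Angpt1, and its high end Dstn, Ctsg, Igsf6, Ms4a3, Clec12a, Elane, Ly6c2, Fcgr3, Cks1b and Emb. Cell 85 was the cell with the fewest detected genes, 2453. Without it the stem list moved from percentile 0 to 11.8 on this component.

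Between the 2 title series, a split of unknown meaning that was not tested, several list medians differed. The secretory list had a median of 0.752% of TPM in plainly numbered cells and 0.536% in R2 cells, and the NADPH oxidase list 0.0849% and 0.125%. Monocyte genes took 0.0566% and 0.0477%, and eosinophil, basophil and mast cell genes 0.0846% and 0.0412%. Stem and multipotent genes took 0.0401% and 0.0200%, megakaryocyte and erythroid genes 0.00869% and 0.0153%, and G2 and M phase genes 0.0597% and 0.0389%. Prg2 was detected in 7 plainly numbered cells and in no R2 cell.

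The 2 cells titled poor quality had fewer genes than any of the 37, with 1433 in cell 78 and 925 in cell 83. In cell 83 Mpo (29611 TPM) and Elane (10804 TPM) were still high and primary granule genes took 5.35% of TPM, but Ctsg was listed at 0. In cell 78 they took 2.20%, while eosinophil, basophil and mast cell genes took 3.45%, from Prg2 at 34127 TPM. Ribosomal RNA precursor sequence annotated as Rn45s took 179762 TPM in cell 78, against at most 9643 TPM in the 37.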

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

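The test of carried-over RNA was chosen after the result was seen. The design holds 1 sorted population and no second group, so no biological explanation was tested by a comparison of groups.

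Cell 78, titled poor quality and left out of the main summaries, held 7 genes at 10000 TPM or more and at least 10 times above the highest of the 37 cells. They were Rn45s (179762 TPM, against at most 9643 TPM), Klk14 (121044 against 406), Gm20594 (69526 against 2196), Ndufa8 (32669 against 884), Pigr (28752 against 92.2), Ear6 (12140 against 0) and Rhox8 (11007 against 95.7). Cell 83 held no gene that passed both limits.

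Transcripts of eosinophils, basophils and mast cells reached very high levels in some of the 37 cells, such as Prg2 in cell 84 (96296 TPM) and Prss34 in cell 95 (59159 TPM). RNA carried over between chambers from 1 source would keep eosinophil and basophil transcripts in a near-constant ratio. The ratio was taken over the 15 cells with at least 100 TPM of Prg2, Prg3, Epx, Mcpt8, Prss34 and Ms4a2 together. With 1 TPM added to each sum, the log2 ratio of the former 3 to the latter 3 spanned 22.9. Its ends were cell 77 (7.20) and cell 72 (-15.7), whose peaks had already been seen. A single source therefore does not account for both kinds of peak. Low amounts carried over from such cells into others cannot be judged, because eosinophil sums near 0 leave the ratio to the basophil amount. For 2 cells captured together, the list score correlated with the number of detected genes at -0.0469, percentile 18.4 among random lists. That lies between the bounds set for this test, and with depth unknown the possibility cannot be told apart from cells of that content.

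Immediate early genes rose with the eosinophil, basophil and mast cell list (rho 0.684). A difference between the title series does not account for it, since rho was 0.592 within the plainly numbered cells and 0.838 within the R2 cells. A linear dependence on the number of detected genes does not account for it either. After a linear term in that number was removed, rho was 0.687, above all 10000 random pairs. The eosinophil, basophil and mast cell score itself correlated with that number at -0.047, so the removal could change little. It cannot decide about a dependence that is not linear. With Pearson correlation the relation lay at percentile 97.4, within the central 95%. Handling of the cells before lysis was not tested and stays open.

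Component 2 rested on cell 85, with high Meis1 (3433 TPM) and Flt3 (1889 TPM). If few detected genes were the cause, other cells with few genes would also show a high share of stem and multipotent genes. Of the other 9 among the 10 cells with the fewest detected genes, 4 lay above the upper quartile of that share, between the bounds set for this test, so a low gene count cannot be told apart from a distinct cell as the source.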

How the results depend on the processing

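Leaving out widely detected genes, leaving out each cell in turn and the random pairs at other thresholds were alternatives chosen after the data were seen. Apart from the cells left out in turn, 821 values of 102 results were recomputed, of which 194 belonged to 24 leading results, and 168 of these stayed within the interval, the percentile bounds or a factor of 1.5. The other 26 follow, and where no reason is given the cause was not tested.

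The detection threshold moved counts by construction. At 5 TPM the median number of genes was 3654, and the shares of cells were 64.9% for the monocyte list, 43.2% for the stem list and 10.8% for Gfi1 with Cebpe. With any value above 0 they were 5334 genes, 97.3% for the monocyte list, 81.1% for the stem list, 32.4% for Gfi1 with Irf8 and 45.9% for Irf8 with Gata2. With 2 members in place of 3, shares rose to 97.3% (monocyte), 86.5% (stem) and 64.9% (eosinophil, basophil and mast cell), and without Ly6c2 and Ms4a6c the monocyte share was 54.1%.

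With all 39 cells, the primary granule and monocyte scores lay at percentile 94.3, and 6 of the 15 most variable genes were shared. In the plainly numbered cells alone these scores lay at percentile 93.4. In the 11 R2 cells alone, the eosinophil, basophil and mast cell share of cells was 9.09%, the primary granule median 3.30% of TPM, and component 1 held 16.7% of the variance, while 6 of the 15 most variable genes were shared. There the primary granule score lay at percentile 24.3 with the stem score and 2.75 with the eosinophil, basophil and mast cell score. Without the 10 cells with the fewest genes, primary granule and stem scores lay at percentile 17.4, and the monocyte list on component 2 reversed to percentile 0. The immediate early relation lay at percentile 97.4 with Pearson correlation. The primary granule median was 3.24% over totals without the 15 most abundant genes, and component 1 held 14.0% of the variance with 200 genes.

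Leaving out each cell in turn moved none of the 24 leading results. For those that are shares of cells or medians this was nearly fixed in advance, since 1 cell can scarcely shift them beyond their intervals. Without each cell, joint detection was followed as shares and was not placed again among random pairs. The co-variation of eosinophil, basophil and mast cell genes then ranged from 0.235 (without cell 84) to 0.359, and the variance of component 1 from 8.87 to 10.2%. Of its values for other results 2839 were the same and 45 moved, among them the stem list on component 1 (percentile 9.6 without cell 72) and megakaryocyte and erythroid co-variation (94.65 without cell 89). Under the remaining alternatives 561 values of other results were the same, 65 moved and 1 reversed, mostly on component 2 and in the R2 cells alone. Depth limits what a 0 means, since it is unknown here and a missed transcript cannot be told from an absent one.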

Other observations

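The test of Gata2 and the choice of the individual cells described here were made after the values were seen; the bounds for Gata1 were set before its result was seen.

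Eosinophil and basophil transcripts peaked in different cells, though the split was incomplete. Cells 84 and 77 held Prg2 at 96296 and 39243 TPM with Epx at 4712 and 538 TPM, and in both Cebpe (269 and 478 TPM) and Gata1 (371 and 579 TPM) were detected. Prss34 stood at 0.6 and 5.03 TPM there, but Mcpt8 at 500 and 286 TPM and Cpa3 at 1898 and 2100 TPM. Cells 95 and 72 instead held Prss34 at 59159 and 31956 TPM, Mcpt8 at 26219 and 20956 TPM and Fcer1a at 3053 and 969 TPM, with Prg2 and Cebpe listed at 0 in both and Gata1 at 217 and 4.22 TPM. Fcer1a was detected in no other cell of the 37. All 4 cells held Mpo, from 7245 TPM in cell 77 to 15705 TPM in cell 84, and 3 of them lay below the median of 10336 TPM, whereas Elane was 4916 and 6025 TPM in cells 84 and 77 and 794 and 23.9 TPM in cells 95 and 72. Antibodies to CCR3 and SiglecF, both eosinophil surface proteins, were in the stain per the labels, but the stated gate does not use them.

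Some cells combined Gata2 and immediate early genes with a low share of primary granule genes. That list took 0.448% of TPM in cell 73 and 0.533% in cell 87, against a median of 2.94%. Cell 87 did not lack all granule genes, since Ctsg stood at 899 TPM and Cpa3 at 2406 TPM. Cell 73 held Gata2 at 2028 TPM, Fos at 8836 TPM and Mpo at 39.3 TPM, and cell 87 held Gata2 at 1386 TPM, Fos at 7426 TPM, Ms4a2 at 4696 TPM and Mpo at 63.6 TPM. After cell 85 these 2 cells had the fewest detected genes of the 37 (2833 and 2890, against a median of 4439), and genes of the secretory pathway took 0.140% and 0.103% of their TPM against a median of 0.728%, and whether library quality gave this pattern was not tested. Gfi1b, which encodes a relative of Gfi1, reached 1466 TPM in cell 87 and 1741 TPM in cell 85. At the other end, cells 82 and 81 held F13a1 at 1265 and 1498 TPM and Irf8 at 334 and 352 TPM beside Elane at 19727 and 5641 TPM, and cell 82 also held Csf1r at 771 TPM.

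A hypothesis is that the eosinophil, basophil and mast cell genes vary together because cells of this gate differ in the regulators of that lineage. Gata2 correlated with the list score at a Spearman rho of 0.696, above all genes of matched mean drawn (percentile 100), and Gata1, which is in another list, at 0.679 (percentile 100). Both lie where that hypothesis puts them, but it was formed and tested on the same cells. Gata2 had already been seen beside Ms4a2 and Cpa3 at the low end of component 1, so its percentile adds little. The relation was also not particular to regulators, since the immediate early score reached a rho of 0.684 with the same list. Single cells ran against the hypothesis too. Cell 84, with the highest list score, held Gata2 at 32.8 TPM, below the median of 51.8 TPM, and Gata1 was listed at 0 in cells 87 and 70 and stood at 4.22 TPM in cell 72, all 3 with high list scores. The correlations do not show which changes first, and cells of these lineages that entered the gate would give the same relation.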
